A study of Rattus norvegicus with 90 samples.

How the data were processed

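Liver RNA of 45 dams and of their fetuses was measured by TempO-Seq, with probes for 21119 genes per the labels and single reads of 50 bases. The 90 libraries fall into 24 groups by liver (maternal or fetal), age and dose. Per the labels, abundant transcripts were attenuated in the same way in all libraries, so levels of the most abundant genes are not comparable with those of other genes. The labels name study blocks 140 and 143 at GD18, each with controls and every dose, and 144 at the later age, with 30 libraries in each block. Age and block are therefore the same split between the ages.

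The deposited estimated counts, 1 column per library for 20833 genes, are not normalised. The submitters' notes name STAR 2.7.3a, Partek and the genome build rn6 without saying what each did, and the way counts were divided between near copies is not stated. Of the estimated counts 7.61% are not whole, spread over 4145 genes, among them Cyp2b1, Cyp2b2, Cyp3a23/3a1, Cyp4a1, Cyp4a2, Cyp4a3, Ephx1 and several haemoglobin genes. The plan had assumed whole counts, and the values were rounded before the tests. The file places Cyp2b1 on chromosome 7, away from Cyp2b2 on chromosome 1, and a model, AABR07035374.1, inside the interval of Cyp3a23/3a1. The second deposited file holds log2 values, which the authors made as log2 of CPM plus 0.0001. It has 18129 genes, those with a mean of at least 1 count per library, and leaves out 2704. All of the 1631610 log2 values checked matched the counts within 0.01. That file was not used for the tests.

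Totals ran from 3184903 to 7265191 counts per library. Between 2 libraries of a group the chi-square per degree of freedom was 7.11 to 179, where counting error alone gives about 1. Genes with few counts were left out of this measure, and some GD18 pairs cross study blocks. For the genes measured, differences between libraries and not depth set the precision. Reads carried no molecular identifiers as far as the labels say.

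Maternal and fetal libraries of each age were fitted apart with edgeR 4.0.16 in R 4.3.3: filterByExpr, TMM factors, quasi-likelihood F tests of each dose against control and of the order of doses as a slope, with study block as a term at GD18. P values were adjusted by Benjamini-Hochberg within each comparison, with a threshold of 0.05, and all tests were two-sided. The SE of a log2 fold change is its size over the square root of F, and fold changes used a prior count of 0.125. Joint fits tested whether the 30 mg/kg/d response differed between dam and fetus within an age, or between ages within a liver. Fetal controls of both ages were compared with each other. Fetal livers were matched to dams by the dam numbers in the labels. As a check of that pairing, the residuals of dam and fetus had a median correlation across genes of 0.06 over 30 pairs at GD18 (−0.641 to 0.426, other dams −0.001) and of 0.052 over 15 pairs at GD21 (−0.038 to 0.121, other dams −0.002). Genes are not independent replicates, and these values are too low to show the pairing.

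Before the data were examined, 33 gene lists were fixed, 20 of biology and 13 of markers, with 682 entries of which 581 are in the file, 1 through an older symbol. The biology lists were AhR, CAR and PXR, NRF2 and PPAR-alpha lipid targets, peroxisomal and mitochondrial beta-oxidation, ketogenesis, fatty acid synthesis, cholesterol biosynthesis, lipoproteins, bile acids, gluconeogenesis, urea cycle, acute phase, complement, cell cycle, p53, ER stress, thyroid hormone and growth hormone. They were tested with camera of limma 3.58.1 at its preset correlation of 0.01, with an estimated correlation, and with fry, which tests whether the genes of a list move one way and compares them with no others. DESeq2 1.42.0 was run on every comparison.

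Named genes were chosen by a rule written before the data were examined. Part 1 took up to 5 rises and 5 falls of largest size at 30 mg/kg/d among genes past the threshold, with a mean log2 CPM of at least 3 and every treated library beyond every control. Part 2 took the 2 called genes of smallest adjusted p in each list, and 4 in the PPAR-alpha and beta-oxidation lists. Part 3 was a fixed set of genes, in every set of libraries, of which Ehhadh, Cyp4a1, Acot1, Pdk4, Cpt1a, Cyp2b1, Cyp7a1, Pck1 and Igfbp1 are reported; the rest of it is not reported here, nor where another part names it, while counts of genes include it. Part 4 took 5 and 5 of each difference of responses and the 5 smallest adjusted p of each slope. Cyp7a1 passed the filter in no set. Genes named outside the rule are said to be so.

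Alternatives tried were RLE factors, no filter on low counts, DESeq2, no block term, each block alone, control and 30 mg/kg/d libraries alone, dose in mg/kg/d as the score, slopes without the 30 mg/kg/d group, dam as a replicate block, and each library left out in turn. Added after the data were seen were covariates for the receptor share, the haemoglobin share and fetal sex (inferred from Y-linked counts), the omission of dam 2135, and slopes within a block. The tests were tested on simulated data, drawn for each gene apart around its mean control level with its fitted spread. Known fold changes put into these counts were found in 78.7% of genes at 4-fold and 46.8% at 2-fold in maternal GD18 liver at 30 mg/kg/d, 73.8% and 43.5% in fetal GD18 liver, 83.1% and 33.8% in maternal GD21 liver, and 64.6% and 6% in fetal GD21 liver. Differences of response were found in 43.8% and 6.3% between dam and fetus at GD18 and 44.4% and 6.6% between ages in fetal liver, with the same control level on both sides. The simulated libraries had no study block effect and no structure shared between genes, such as a differing receptor or haemoglobin share. The shares found may therefore differ in the real libraries. Reads were not remapped and no genome sequence was used. No library was left out.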

Results

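Transcripts were counted in liver of pregnant Sprague-Dawley rats and of their fetuses after oral dosing of the dams with Nafion byproduct 2 (NBP2), a polyfluorinated ether sulfonic acid. The assay, TempO-Seq, ligates detector probes that lie side by side on a transcript and sequences the ligated product, so each gene is read at its probe site only. Dams dosed from GD14 were sampled at GD18, with 6 controls and 4 dams at each of 30, 10, 3, 1, 0.3 and 0.1 mg/kg/d. Dams dosed from GD17 were sampled at a later age, with 3 controls and 3 dams at each of 30, 10, 3 and 1 mg/kg/d. The titles and the treatment text call the later age GD21, while its age entry and the design text call it GD20. It is called GD21 here. Each of the 45 dams gave 1 maternal and 1 fetal library, which makes 90 libraries in 24 groups. Whether a fetal library came from 1 fetus or several, and of which sex, is not stated.

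Total counts ran from 3184903 in the fetal GD21 library of dam 2135 at 3 mg/kg/d to 7265191 in the fetal GD18 library of dam 2121 at 1 mg/kg/d. The library of dam 2135 held 8982 genes with a count, against 12503 or more in the other 14 fetal GD21 libraries. Haemoglobin transcripts took 3.96% to 17.4% of the counts in fetal libraries and 0.042% to 0.773% in maternal libraries. The file places 1241 genes in the olfactory, vomeronasal and taste receptor families, which liver is not known to express. In the 15 maternal GD18 libraries of study block 140 these receptors took 663 to 5530 CPM (counts scaled to an equal total per library), and in the 15 fetal libraries of that block 121.6 to 5323 CPM. In study block 143 they took at most 51.3 CPM in maternal and 36.9 CPM in fetal GD18 libraries. The GD21 libraries, all of study block 144, held at most 34.8 CPM in maternal and 365 CPM in fetal liver. The 365 CPM were in control fetus 2129, where 812 of the receptor genes had a count.

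**Figure D1:**
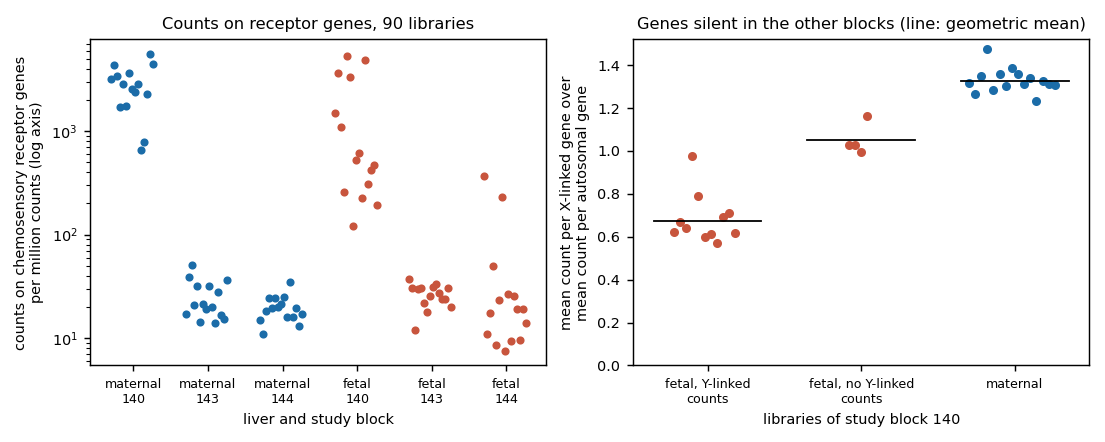
Left, CPM (log axis) of olfactory, vomeronasal and taste receptor genes in each of the 90 libraries, by liver and study block; right, mean count of silent X-linked genes over that of silent autosomal genes in the GD18 libraries of block 140, with lines at geometric means. Block 140 reached 5530 CPM against at most 51.3 CPM in block 143, and the ratio averaged 0.674 in 11 fetal libraries with Y-linked counts, 1.05 in 4 without and 1.33 in 15 maternal libraries.

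The comparison of maternal liver at GD18 between 30 mg/kg/d (n = 4) and control (n = 6) asked which transcripts the highest dose changed in the dam. Large rises were in cytochrome P450 genes that the xenobiotic receptors CAR and PXR are known to induce. Cyp2b2 rose by a log2 fold change of 7.03 ± 0.93 (SE), from 9.87 ± 10.9 to 904 ± 721 CPM (mean ± SD), with an adjusted p of 3.74e-05. Cyp2b1, its close paralog and the usual readout of CAR, rose by 4.86 ± 0.54 (adjusted p 1.43e-06), from 30.8 ± 18.8 to 847 ± 476 CPM. Cyp3a23/3a1, the usual readout of PXR, rose by 4.52 ± 0.43 (adjusted p 1.2e-07), from 132.2 ± 24.8 to 3105 ± 1272 CPM. The smallest adjusted p, 5.04e-09, belonged to Ephx1, the microsomal epoxide hydrolase, which rose by 2.10 ± 0.17. Genes of fatty acid oxidation rose as well: Acot1, an acyl-CoA thioesterase induced through PPAR-alpha, by 5.21 ± 0.77 (adjusted p 0.000171), and Ehhadh, the peroxisomal bifunctional enzyme, by 2.15 ± 0.23 (adjusted p 5.27e-07), from 44.5 ± 7.24 to 199.5 ± 79.1 CPM. Each of these 6 genes was higher in 4 of 4 treated libraries than in every control library, an order that the naming rule required of genes taken by size. Acot1 was not taken by size, because its mean log2 CPM was under 3, so its large fold change starts from a low level.

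In all, edgeR called 63 of 13783 tested genes in maternal GD18 liver at 30 mg/kg/d, 48 higher and 15 lower. Other large rises were in Dhrs7l1, a short-chain dehydrogenase, by 3.41 ± 0.48 (adjusted p 7.97e-05), and in AABR07035374.1, an unnamed model inside the Cyp3a23/3a1 interval, by 4.25 ± 0.43 (adjusted p 3.39e-07). The largest falls were in haemoglobin genes and in Fmo1, a flavin monooxygenase. Hbb-bs fell by 2.08 ± 0.49 (adjusted p 0.0481), from 1443 ± 1125 to 346.5 ± 190.7 CPM, beside its overlapping model LOC100134871, which fell by 2.09 ± 0.50 (adjusted p 0.0481). Hba-a2 fell by 1.82 ± 0.43, Hba-a3 fell by 1.74 ± 0.40 and Fmo1 fell by 1.89 ± 0.42 (adjusted p 0.0479, 0.0386 and 0.0325). Cyp2b1, Cyp2b2, Cyp3a23/3a1, Ephx1 and the haemoglobin genes other than Hba-a3 have counts split between near copies, so the share of each copy is uncertain.

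In the file, on the build rn6, Cyp2b2 lies on chromosome 1 from 83103925 to 83119194 and Cyp2b1 on chromosome 7 from 99142450 to 99181784. Cyp3a23/3a1 lies on chromosome 12 from 11655402 to 11733137, Ephx1 on chromosome 13 from 99271366 to 99300580, Acot1 on chromosome 6 from 107485249 to 107493799 and Ehhadh on chromosome 11 from 82945104 to 82978365. Within study blocks 140 and 143 taken alone, the log2 fold changes were 9.56 (adjusted p 0.0686) and 5.94 for Cyp2b2, 4.00 and 5.58 for Cyp2b1, 4.22 and 4.78 for Cyp3a23/3a1, 1.88 and 2.23 for Ephx1, 4.47 and 6.69 for Acot1, and 2.45 and 1.80 for Ehhadh. The count of 63 became 13 within block 140 and 29 within block 143. It was 38 without control dam 2070, 40 without control dam 2114, 23 without treated dam 2127 and 124 without treated dam 2083. The calls of Cyp2b2, Cyp2b1, Cyp3a23/3a1, Dhrs7l1, Ephx1, Acot1 and Ehhadh held when any of the 10 libraries was left out, with Cyp2b2 at 6.03 without treated dam 2083. Those of LOC100134871, Hbb-bs, Fmo1, Hba-a2 and Hba-a3 each ended in 6 of the 10 such fits, with adjusted p up to 0.193 for Hba-a2 without treated dam 2082.

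The CAR and PXR target list had 9 members that rose, none that fell and 11 not called (14 rose and 1 fell adjusted over the list alone). Among them, Slco1a4, an organic anion carrier, rose by 1.46 ± 0.22 (adjusted p 0.000193). Mitochondrial beta-oxidation had 4 members that rose and 19 not called (14 rose adjusted over the list alone): Acot2 by 2.22 ± 0.25, Eci1 by 2.09 ± 0.29, Hadha by 0.78 ± 0.14 and Acadm by 0.92 ± 0.21. Peroxisomal beta-oxidation had 4 that rose and 14 not called (8 adjusted over the list alone), among them Acot4, a peroxisomal thioesterase, at 1.47 ± 0.27 and Acox2, a branched-chain oxidase, at 0.90 ± 0.19. Of the PPAR-alpha lipid targets 5 rose, 1 fell and 20 were not called (10 rose and 1 fell adjusted over the list alone). Vnn1, a pantetheinase, rose by 2.42 ± 0.24 and Pdk4, which restrains glucose oxidation, by 1.35 ± 0.30, while Rgn, the calcium-binding regucalcin, fell by 0.98 ± 0.18 against the direction of its list. Of the NRF2 targets 2 rose and 16 were not called (7 rose and 1 fell adjusted over the list alone), Ephx1 and Blvrb, a biliverdin reductase, by 0.79 ± 0.17. Ugt1a6, a glucuronosyltransferase, rose by 1.04 ± 0.18, Cyp2c11, a growth hormone dependent P450, by 2.00 ± 0.45, and Gadd45a, a stress gene, by 0.81 ± 0.18. Without dam 2127 the adjusted p of Rgn was 0.0686, of Ugt1a6 0.108 and of Acox2 0.115, and without dam 2128 that of Acox2 was 0.128. The calls of Acadm, Gadd45a, Pdk4, Cyp2c11 and Blvrb ended in 9, 7, 6, 6 and 4 of the 10 fits that left out 1 library, with log2 fold changes down to 0.41 for Acadm without dam 2082 (adjusted p 0.472) and 0.47 for Gadd45a without dam 2127 (adjusted p 0.323).

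By camera with its preset correlation, 11 of 33 lists differed from other genes in maternal GD18 liver. CAR and PXR targets (adjusted p 5.46e-39, and 1.82e-06 with an estimated correlation), mitochondrial beta-oxidation (1.98e-14 and 0.000109), peroxisomal beta-oxidation (1.41e-13 and 0.000109), NRF2 targets (2.98e-09 and 0.000382) and PPAR-alpha lipid targets (3.42e-09 and 0.000109) were higher under both. The NRF2 list as fixed shares Ephx1, Gsta3 and Akr7a3 with the CAR and PXR list, and it was not tested without them. Bile acid synthesis and transport and AhR targets were higher, with adjusted p = 0.0779 each with an estimated correlation. Fatty acid synthesis (median log2 fold change −0.32), gluconeogenesis and glycogen (−0.22), erythroid markers (−0.26) and macrophage and Kupffer cell markers (−0.25) were lower with the preset correlation. Their adjusted p with an estimated correlation were 0.144, 0.0779, 0.453 and 0.453. The other 22 lists had adjusted p of 0.21 to 0.946. Among them, median and mean log2 fold change differed in sign for cholesterol biosynthesis, complement and coagulation, immediate early and heat shock genes, mature hepatocyte genes, stellate and fibroblast markers, and urea cycle and amino acid breakdown.

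Of the genes fixed in advance, Cyp4a1, a fatty acid hydroxylase induced through PPAR-alpha, was not called in maternal liver at GD18 (0.80 ± 0.21, adjusted p 0.0877), although it was above every control in 4 of 4 libraries. Cpt1a (0.40 ± 0.31), Pck1 (1.23 ± 0.48) and Igfbp1 (1.03 ± 0.58) were not called either, with adjusted p of 0.706, 0.334 and 0.565.

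In maternal liver at GD18 the lower doses asked where in the range the response began. At 10 mg/kg/d edgeR called 6 genes, beside a median log2 fold change of −0.11 over all genes, and 4 of them were higher: Cyp2b2 by 5.15 ± 0.89, Cyp2b1 by 2.96 ± 0.51, Cyp3a23/3a1 by 2.29 ± 0.40 (adjusted p 0.0168 each) and AABR07035374.1 by 2.22 ± 0.42 (adjusted p 0.0261). The 2 lower genes, LOC499219 and the olfactory receptor Olr1369, lie outside the naming rule and were named after their values were seen. Olr1369 is one of the receptor genes whose counts were high in block 140. On these genes the dams of that block at 10 mg/kg/d had 783.1 and 2294 CPM. Its control dams had 3211, 4350 and 3403 CPM. With the receptor share as covariate, chosen after seeing the data, 0 genes were called at 10 mg/kg/d. The count of 6 was 1 without control dam 2070, 0 without control dams 2114 or 2115, 3 without control dam 2116 and 0 without treated dam 2125, and 0 within either study block. At 3 mg/kg/d edgeR called 0 genes (986 at an unadjusted p under 0.05, 11 by DESeq2), with Cyp2b2 closest at 5.04 and an adjusted p of 0.0558. It called 100 genes there without treated dam 2078, 8 of them higher, and 3 without treated dam 2124. At 1, 0.3 and 0.1 mg/kg/d edgeR called 0 genes each (352, 325 and 646 at an unadjusted p under 0.05, 0 each by DESeq2), and 1 gene at 1 mg/kg/d without treated dam 2121. Along the order of doses 30 genes had a slope, 28 upward. Cyp3a23/3a1 rose by 0.69 ± 0.07 log2 units per dose step (adjusted p 1.84e-07), Cyp2b1 by 0.76 ± 0.08, AABR07035374.1 by 0.65 ± 0.07, Cyp2b2 by 1.08 ± 0.12 and Ephx1 by 0.30 ± 0.04. The slopes of these 5 genes were called with any library left out. With the 30 mg/kg/d group left out, 6 genes had a slope.

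The comparison of fetal liver at GD18 between 30 mg/kg/d (n = 4) and control (n = 6) asked which transcripts changed in the fetus of dosed dams. Fatty acid genes led the response. Ehhadh rose by a log2 fold change of 2.64 ± 0.28 (SE, adjusted p 3.22e-06), from 2.35 ± 0.785 to 14.6 ± 5.22 CPM (mean ± SD), and Acot1 by 2.61 ± 0.35 (adjusted p 8.16e-05), from 2.49 ± 1.16 to 15.3 ± 5.91 CPM. Fabp1, the liver fatty acid binding protein, rose by 2.48 ± 0.27 (adjusted p 4.02e-06), from 71.1 ± 21.3 to 388.2 ± 62.6 CPM. Cyp4a3 and Cyp4a2, fatty acid hydroxylases with near-identical copies, rose by 2.49 ± 0.24 and 2.29 ± 0.32 (adjusted p 7.39e-07 and 0.000219). Cyp3a23/3a1 rose by 2.53 ± 0.28 (adjusted p 4.26e-06), from 6.35 ± 1.39 to 36.7 ± 10.3 CPM. All 4 treated libraries were above every control library for each of these 6 genes. The rule required this order of Fabp1, Cyp4a3, Cyp4a2 and Cyp3a23/3a1, which were taken by size. It did not require it of Ehhadh and Acot1, whose mean log2 CPM was under 3.

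Altogether edgeR called 13 of 12659 tested genes in fetal GD18 liver at 30 mg/kg/d, 13 higher and 0 lower. With fetal sex, inferred from Y-linked counts, as covariate, chosen after seeing the data, the count was 260, 21 of them higher, and with the receptor share as a further covariate 11; at 10 mg/kg/d these fits called 151 and 0 genes, where the fit without covariates called 0. Others were AABR07035374.1 (2.57 ± 0.29), Lpl, lipoprotein lipase (0.51 ± 0.11, adjusted p 0.0432), Vnn1 (1.31), the lipid droplet protein Hsd17b13 (1.13) and the fatty acid ester hydrolase Adtrp (0.99). The last 3 fall outside the naming rule and were named after their values were seen. Within study blocks 140 and 143 the log2 fold changes were 2.60 and 2.89 for Ehhadh, 2.96 and 2.41 for Acot1, 2.83 and 2.21 for Fabp1, 2.95 and 2.12 for Cyp4a3, and 2.82 and 2.38 for Cyp3a23/3a1. The count was 3 within block 140 and 4 within block 143, and 9 to 12 with 1 library left out. The call of Lpl ended with any of the 10 libraries left out (adjusted p 0.06 to 0.97). Fabp1 lies on chromosome 4 from 99063181 to 99066955, Cyp4a2 on chromosome 5 from 134196912 to 134207864 and Cyp4a3 on chromosome 5 from 134469270 to 134484840.

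The PPAR-alpha lipid target list had 5 members that rose, none that fell and 20 not called in fetal GD18 liver (8 rose adjusted over the list alone). Peroxisomal beta-oxidation had 2 that rose and 12 not called (4 rose adjusted over the list alone). Mitochondrial beta-oxidation had none called of 22 (8 rose adjusted over the list alone). Of the CAR and PXR targets only Cyp3a23/3a1 was called, with 15 not called (3 rose adjusted over the list alone). Camera with its preset correlation called 9 of 33 lists, all higher than other genes. PPAR-alpha lipid targets (adjusted p 2.73e-19, and 7.67e-08 with an estimated correlation), mitochondrial beta-oxidation (8.22e-14 and 0.000111), peroxisomal beta-oxidation (5.41e-11 and 9.4e-05), ketogenesis (5.54e-06 and 0.00125), fatty acid synthesis (1.53e-06 and 0.00509) and lipoproteins and lipid transport (2.65e-06 and 0.0238) held under both. Cholesterol biosynthesis, complement and coagulation, and acute phase proteins did not, with adjusted p = 0.0939, 0.0504 and 0.523 with an estimated correlation. The other 24 lists had adjusted p of 0.053 to 0.982, and CAR and PXR targets had 0.067. For 14 lists, none of them called, the camera direction, the median and the mean differed in sign. For CAR and PXR targets the direction was up, with a median of −0.12 and a mean of −0.04.

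Cyp2b1 was not called in fetal GD18 liver at 30 mg/kg/d (2.50 ± 0.83, adjusted p 0.473, 1.68 ± 2.04 CPM in controls and 4.61 ± 3.31 CPM in treated fetuses). Cpt1a (0.58 ± 0.31) and Igfbp1 (−0.11 ± 0.37) were not called either, and Cyp4a1, Pdk4, Pck1 and Cyp7a1 were below the expression filter there. At 10, 3, 1, 0.3 and 0.1 mg/kg/d edgeR called 0 genes each, with 863, 326, 514, 229 and 418 at an unadjusted p under 0.05, and DESeq2 called 0, 0, 0, 0 and 3. At 10 mg/kg/d Fabp1 stood at 0.83 ± 0.27 and Cyp3a23/3a1 at 1.02 ± 0.30, both with an adjusted p of 0.727. Along the order of doses 11 genes had a slope, 8 upward. They included Acot1 (0.43 ± 0.07 log2 units per step), AABR07035374.1 (0.38 ± 0.05), Cyp4a3 (0.37 ± 0.05), Cyp3a23/3a1 (0.35 ± 0.05) and Fabp1 (0.33 ± 0.05), with adjusted p of 0.000218 to 0.000542. The number of slopes was 858 without the 3 mg/kg/d fetus 2079, 46 of them upward, 0 without the 30 mg/kg/d group and 0 within either study block.

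**Figure D2:**
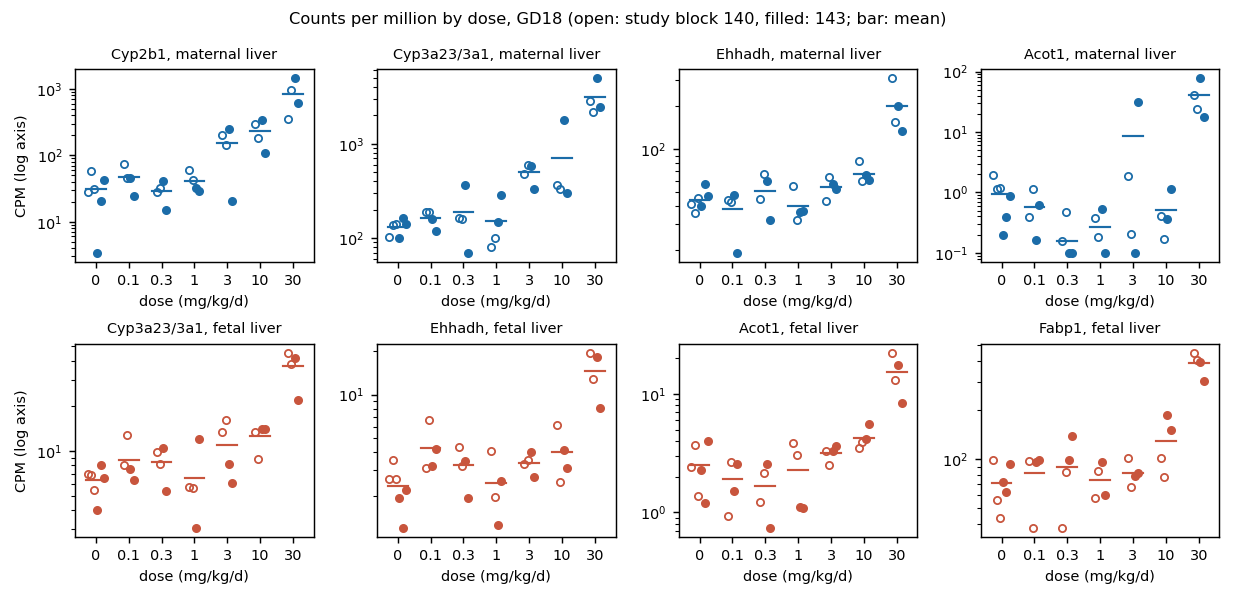
CPM (log axis, values under 0.1 drawn at 0.1) of 4 genes in maternal and 4 in fetal liver at GD18 by dose in mg/kg/d, 1 point per library (open, study block 140; filled, study block 143), with bars at group means. At 30 mg/kg/d Cyp3a23/3a1 averaged 3105 CPM in dams and 36.7 CPM in fetuses, against 132.2 and 6.35 CPM in controls.

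The comparison of maternal liver at GD21 between 30 mg/kg/d and control (n = 3 each) asked the same question for the later dosing. Cyp2b1 rose by a log2 fold change of 5.91 ± 0.39 (SE, adjusted p 6.72e-07), from 21.7 ± 2.89 to 1305 ± 675 CPM (mean ± SD), and Cyp2b2 by 5.74 ± 0.56 (adjusted p 7.21e-05). Cyp3a23/3a1 rose by 4.65 ± 0.47 (adjusted p 7.53e-05), from 170.3 ± 15.1 to 4276 ± 2436 CPM. Cyp4a1 rose by 2.14 ± 0.26 (adjusted p 0.000491), from 120.4 ± 26.1 to 531 ± 127.8 CPM, and Ehhadh by 2.46 ± 0.30 (adjusted p 0.000491). Each was higher in 3 of 3 treated libraries than in every control library, an order that the naming rule required of genes taken by size.

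At this age edgeR called 31 of 9238 tested genes in maternal liver at 30 mg/kg/d, 28 higher and 3 lower. Rises also covered AABR07035374.1 (4.77 ± 0.38), Dhrs7l1 (4.67 ± 0.55), Ephx1 (2.08 ± 0.25), Acot1 (4.96 ± 0.98), Acot2 (2.13 ± 0.41), Eci1 (1.95 ± 0.32), Slco1a4 (1.61 ± 0.29) and Ugt1a6 (1.49 ± 0.23). Gcnt2, a glycan-branching enzyme, fell by 1.10 ± 0.20 (adjusted p 0.0208), Lclat1, a cardiolipin acyltransferase, fell by 1.00 ± 0.19 (adjusted p 0.0297), and Gnpnat1, of hexosamine synthesis, fell by 0.98 ± 0.20 (adjusted p 0.0427). The count was 12 without control dam 2129, 13 without control dam 2130, 55 without treated dam 2141, 10 without treated dam 2142 and 15 without treated dam 2143. The calls of Cyp2b1, Cyp2b2, Cyp3a23/3a1, AABR07035374.1, Dhrs7l1, Ephx1, Cyp4a1 and Ehhadh held with any of the 6 libraries left out. Lclat1 lost its call in 6 of those fits, Gcnt2 and Gnpnat1 in 5, Acot1, Acot2 and Slco1a4 in 4, and Eci1 and Ugt1a6 in 2, with adjusted p up to 0.296 for Gnpnat1 without dam 2143. The log2 fold change of Acot1 ran from 4.05 without treated dam 2143 to 11.63 without control dam 2131. Pdk4 (1.59 ± 0.38, adjusted p 0.123), Cpt1a (0.71 ± 0.34), Pck1 (0.42 ± 0.51) and Igfbp1 (1.45 ± 0.63) were not called.

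Of the CAR and PXR targets 10 rose, none fell and 10 were not called in maternal GD21 liver (14 rose and 1 fell adjusted over the list alone). The PPAR-alpha lipid targets had 3 that rose and 21 not called (12 rose adjusted over the list alone), and peroxisomal and mitochondrial beta-oxidation 2 that rose each (10 each adjusted over the list alone). Camera called 8 of 32 lists with its preset correlation. CAR and PXR targets (adjusted p 2.23e-55, and 0.000233 with an estimated correlation), peroxisomal beta-oxidation (7.6e-17 and 0.0084), PPAR-alpha lipid targets (1.11e-13 and 0.00457) and mitochondrial beta-oxidation (9.2e-13 and 0.02) were higher under both. NRF2 targets, bile acid synthesis and transport, and AhR targets were higher and complement and coagulation lower (median −0.17) with the preset correlation alone. These had adjusted p = 0.228, 0.124, 0.124 and 0.228 with an estimated correlation. The other 24 lists had adjusted p of 0.103 to 0.977. Median, mean and direction differed in sign for ER stress and integrated stress response, mature hepatocyte genes, stellate and fibroblast markers, and thyroid hormone handling and response.

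At 10 mg/kg/d edgeR called 5 genes in maternal GD21 liver, all higher: Cyp2b1 by 4.16 ± 0.36 (adjusted p 3.72e-05), Cyp2b2 by 4.14 ± 0.52, Dhrs7l1 by 3.39 ± 0.53, AABR07035374.1 by 3.35 ± 0.36 and Cyp3a23/3a1 by 3.08 ± 0.43 (adjusted p 0.00219, 0.0161, 0.000367 and 0.00629). The count was 3 without control dam 2129 and 3 without control dam 2131. At 3 and 1 mg/kg/d edgeR called 0 genes each, with 366 and 806 at an unadjusted p under 0.05 and 5 and 4 by DESeq2. Along the order of doses 41 genes had a slope, 37 upward, led by Cyp2b1 (1.49 ± 0.10 log2 units per step, adjusted p 6.95e-08), Cyp2b2 (1.45 ± 0.10), AABR07035374.1 (1.26 ± 0.10), Cyp3a23/3a1 (1.22 ± 0.12) and Ephx1 (0.50 ± 0.07). The slopes of these 5 genes were called with any library left out, while the number of slopes was 19 without treated dam 2142, 22 without treated dam 2143 and 4 without the 30 mg/kg/d group.

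The comparison of fetal liver at GD21 between 30 mg/kg/d and control (n = 3 each) found 3 genes by edgeR among 10244 tested, all higher. Acot1 rose by a log2 fold change of 5.78 ± 0.72 (SE, adjusted p 0.00325), from 2.09 ± 0.39 to 115.1 ± 83.8 CPM (mean ± SD). Ehhadh rose by 4.11 ± 0.56 (adjusted p 0.00667), from 12.9 ± 4.33 to 222.8 ± 176.5 CPM, and Fabp1 by 3.08 ± 0.37 (adjusted p 0.00325), from 276.8 ± 64.7 to 2332 ± 984 CPM. All 3 treated libraries were above all 3 controls for each gene, an order that the naming rule required of genes taken by size. The calls, more than the changes, depended on single controls: for Acot1, Ehhadh and Fabp1 the log2 fold changes were 5.85, 4.16 and 2.92 without fetus 2129 (adjusted p 0.0519, 0.0853 and 0.0519), and 5.63, 4.35 and 3.07 without fetus 2130 (adjusted p 0.0574 each). The count was 0 without either of these, 7 without control fetus 2131 and 20 without treated fetus 2141, and DESeq2 called 26 genes. Haemoglobin took 16%, 12.8% and 3.96% of the counts in the control fetuses 2129, 2130 and 2131 and 14.2%, 5.12% and 5.09% in the treated fetuses 2141, 2142 and 2143. With that share as covariate, chosen after seeing the data, 4 genes were called; Acot1 stood at 5.39 ± 0.76 (adjusted p 0.0237), Fabp1 at 2.83 ± 0.30 (adjusted p 0.00169) and Ehhadh at 3.81 ± 0.65 (adjusted p 0.0726), short of the threshold with a smaller change and a wider SE. Other fixed genes did not pass the test: Cyp2b1 (4.96 ± 1.10, adjusted p 0.218), Cyp4a1 (3.85 ± 0.80, adjusted p 0.185), Igfbp1 (1.61 ± 0.35, adjusted p 0.189) and Pck1 (3.66 ± 1.19, adjusted p 0.9996). Cpt1a (1.53 ± 0.54) and Pdk4 (0.53 ± 0.75) were not called either.

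At 10, 3 and 1 mg/kg/d edgeR called 0 genes each in fetal GD21 liver, with 388, 474 and 63 at an unadjusted p under 0.05 and 11, 1 and 0 by DESeq2. At 10 mg/kg/d Acot1 stood at 4.24 ± 0.68 (adjusted p 0.0765) and Fabp1 at 2.38 ± 0.36 (adjusted p 0.0756). Along the order of doses 17 genes had a slope, 14 upward. They were led by Acot1 (1.58 ± 0.15 log2 units per step, adjusted p 2.27e-05), Fabp1 (0.77 ± 0.08, adjusted p 3.67e-05), Ehhadh (0.99 ± 0.14), the stearoyl-CoA desaturase Scd (0.57 ± 0.08) and Cyp4a2 (0.58 ± 0.09). Cyp2b1 (1.25 ± 0.21, adjusted p 0.00988) and Cyp4a1 (0.98 ± 0.17, adjusted p 0.017) had upward slopes too. The slopes of the first 5 genes were called with any library left out. The number of slopes was 9 without control fetus 2129, 27 without control fetus 2131, 7 without treated fetus 2142, 7 without treated fetus 2143 and 5 without the 30 mg/kg/d group.

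Camera called 13 of 33 lists in fetal GD21 liver with its preset correlation, 2 with an estimated one, and fry called 0. The lists were not tested with the haemoglobin share as covariate. PPAR-alpha lipid targets had 2 members that rose and 24 not called (8 rose adjusted over the list alone), with a camera adjusted p of 2.01e-19 and 0.0208 with an estimated correlation. Fatty acid synthesis, with none called of 16 and 1 that rose adjusted over the list alone, had 8.75e-07 and 0.0208. Peroxisomal beta-oxidation (1 rose, 13 not called, 3 rose adjusted over the list alone), mitochondrial beta-oxidation and ketogenesis (none called, 4 and 2 rose adjusted over the list alone), cholesterol biosynthesis and cell cycle were higher, with adjusted p = 0.078, 0.29, 0.188, 0.305 and 0.36 with an estimated correlation. Acute phase proteins, urea cycle and amino acid breakdown, neutrophil and granulocyte precursor markers, megakaryocyte and platelet markers, bile acid synthesis and transport, and complement and coagulation were lower. With an estimated correlation these had adjusted p = 0.36, 0.328, 0.232, 0.328, 0.335 and 0.626. The other 20 lists had adjusted p of 0.0883 to 0.855, with median, mean or direction at odds in sign for ER stress and integrated stress response, NRF2 targets, growth hormone, prolactin and IGF axis, immediate early and heat shock genes, lipoproteins and lipid transport, and mature hepatocyte genes.

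**Figure D3:**
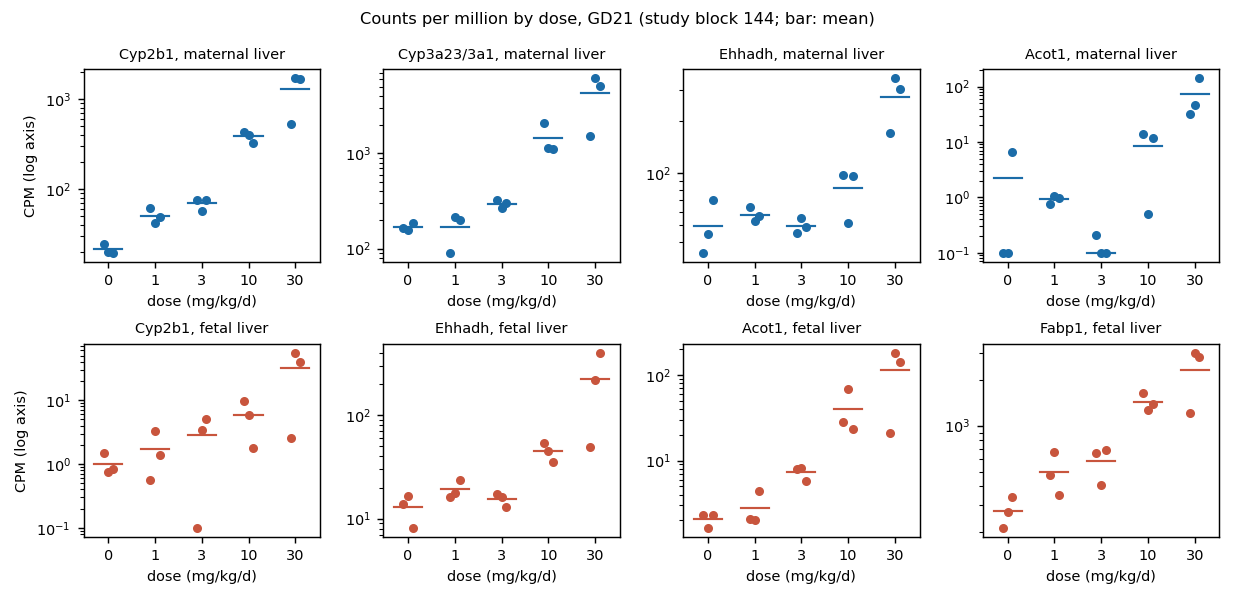
CPM (log axis) of 4 genes in maternal and 4 in fetal liver at GD21 by dose in mg/kg/d, 1 point per library, with bars at group means. Fabp1 averaged 2332 CPM in fetuses at 30 mg/kg/d against 276.8 CPM in controls, and Cyp2b1 1305 against 21.7 CPM in dams.

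**Figure D4:**
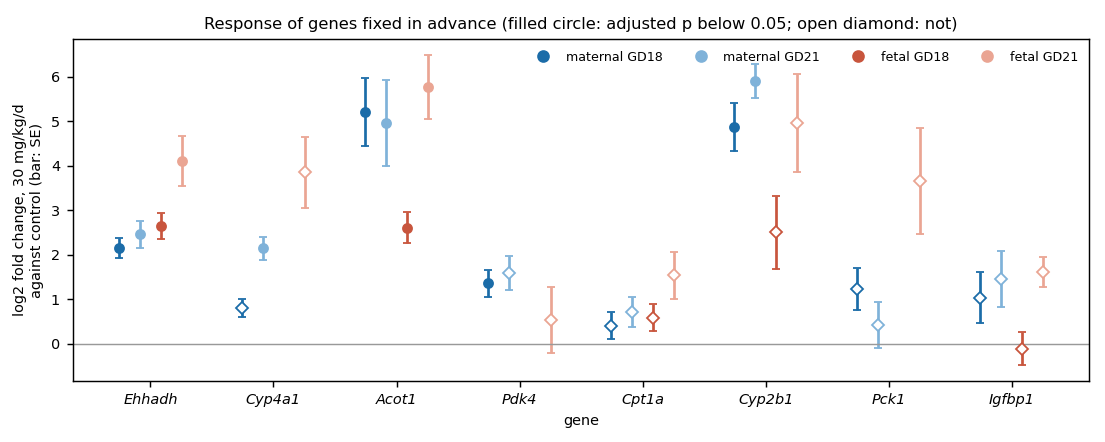
Log2 fold change of 30 mg/kg/d against control, with bars of 1 SE, of genes fixed in advance in the 4 sets of libraries; filled circles have an adjusted p under 0.05 and open diamonds do not. Ehhadh and Acot1 were called in all 4 sets, and Cyp2b1 in maternal liver at both ages.

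A test of the difference between the fetal and the maternal 30 mg/kg/d responses asked which genes responded unequally. At GD18 edgeR called 14 of 15702 genes (3080 at an unadjusted p under 0.05), 8 with the more positive response in the fetus. Cyp4a3 differed by a log2 value of 2.91 ± 0.37 (SE, adjusted p 2.84e-06), with a response of 2.49 in the fetus and −0.30 in the dam. Cyp4a2 differed by 2.69 ± 0.38 (adjusted p 2.87e-05, 2.29 against −0.28) and Fabp1 by 2.58 ± 0.40 (adjusted p 0.000158, 2.48 against 0.03). Responses more positive in the dam were those of Ephx1 (difference −1.50 ± 0.27, adjusted p 0.00217, 0.48 in the fetus against 2.10 in the dam), Dhrs7l1 (−5.40 ± 1.02, adjusted p 0.00488, −1.92 against 3.41), Slco1a4 (−3.24 ± 0.68, −1.58 against 1.46), the stress cytokine Gdf15 (−2.80 ± 0.60, −1.06 against 1.86) and Eci1 (−1.79 ± 0.39, 0.15 against 2.09). None of these 5 was called in the fetus, where Dhrs7l1, Slco1a4 and Gdf15 had adjusted p of 0.555, 0.576 and 0.556. In block 140 the fetuses at 30 mg/kg/d had less on receptor genes (469.7 and 194.7 CPM) than control fetuses (1087 CPM or more). Its dams at 30 mg/kg/d had more (4428 and 5530 CPM) than control dams (at most 4350 CPM). Whether this uneven background adds to the differences of Dhrs7l1, Slco1a4 and Gdf15 is left open. With the receptor share as covariate the number of genes called at GD18 stayed within 1.5 times. Fmo1 and Hba-a3, which fell in the dam, differed by 2.21 ± 0.46 and 2.25 ± 0.49. With dam as a replicate block, which pairs each fetal liver with its own dam, 10 genes were called at GD18. Cyp4a3, Cyp4a2, Fabp1, Fmo1, Dhrs7l1 and Ephx1 stayed past the threshold (adjusted p 0.000924, 0.000924, 0.00108, 0.0208, 0.00232 and 0.031), while Hba-a3, Slco1a4, Gdf15 and Eci1 did not (0.257, 0.242, 0.133 and 0.13).

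The differences of Cyp4a3, Cyp4a2, Fabp1 and Ephx1 at GD18 were called with any of the 20 libraries left out. That of Dhrs7l1 ended in 3 of these fits, Slco1a4 in 4, Fmo1 in 5, Gdf15 in 8, Eci1 in 12 and Hba-a3 in 13, with adjusted p up to 0.418 for Slco1a4. The count of 14 was 7 without control fetus 2070, 8 without treated fetus 2082, 7 without treated fetus 2083 and 8 without treated dam 2127. Raised in dam and fetus alike at GD18 were 6 genes, among them AABR07035374.1, Acot1, Cyp3a23/3a1, Ehhadh and Vnn1, where independent lists would share 0.048. Of the 57 genes called in the dam and tested in the fetus, 31 had the same sign there. Cyp3a23/3a1 was not among the genes whose responses differed, although it rose by 4.52 in the dam and 2.53 in the fetus.

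At GD21 the same test by edgeR called 4 of 10794 genes: Fabp1, larger in the fetus by 2.82 ± 0.44 (adjusted p 0.00876), and Gstm7 (−2.22 ± 0.38, −0.94 in the fetus against 1.29 in the dam), Ephx1 (−1.80 ± 0.33, 0.28 against 2.08) and Gsta2 (−3.10 ± 0.58, −1.53 against 1.57), more positive in the dam, the last 3 of them detoxifying enzymes and none of them called in the fetus. With dam as a replicate block 0 genes were called, with adjusted p of 0.0953, 0.0727, 0.0953 and 0.0953. Without the block DESeq2 called 7. The count was 2 without control fetus 2129, treated fetus 2142 or control dam 2129. It was 1 without treated fetus 2141 or 2143, control dam 2130 or 2131 or treated dam 2142, and 0 without control fetus 2130 or treated dam 2143. The call of Fabp1 ended in 2 of these 12 fits, that of Gstm7 in 7, that of Ephx1 in 10 and that of Gsta2 in 12. Acot1 and Ehhadh were raised in dam and fetus alike at GD21, where independent lists would share 0.008 genes, and 23 of the 27 genes called in the dam and tested in the fetus had the same sign there.

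Between the ages the question was whether the response to 30 mg/kg/d changed with the later dosing. Maternal liver gave 0 genes by edgeR among 14621 (622 at an unadjusted p under 0.05, 0 by DESeq2), and 21 genes rose at both ages, where independent lists would share 0.146. They included Cyp2b1, Cyp2b2, Cyp3a23/3a1, Ephx1, Acot1, Acot2, Ehhadh, Eci1 and Slco1a4, and 61 of the 63 genes called at GD18 had the same sign at GD21. Fetal liver gave 0 genes by edgeR among 14697 (302 at an unadjusted p under 0.05, 2 by DESeq2). In simulated libraries without structure shared between genes this test found 44.4% of 4-fold differences of response and 6.6% of 2-fold ones. The count in fetal liver was 5 without treated GD21 fetus 2141 and 1 without control GD21 fetus 2131. Acot1, Ehhadh and Fabp1 rose at both ages in the fetus, where independent lists would share 0.004, and 13 of the 13 genes called at GD18 had the same sign at GD21.

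Fetal control livers of GD21 (n = 3) and GD18 (n = 6) were compared to describe the change with age alone, which study block cannot be told apart from. The plasma protein Azgp1 rose by a log2 fold change of 7.99 ± 0.58 (SE, adjusted p 1e-05), from 1.83 ± 1.55 to 474 ± 315 CPM (mean ± SD). The fibrinogen gene Fgg rose by 3.60 ± 0.16 (adjusted p 8.44e-07), from 1867 ± 228 to 22650 ± 3539 CPM, and the methionine cycle enzyme Mat1a by 3.78 ± 0.19 (adjusted p 1.44e-06). The early haemoglobins Hbg1 and Hbe1 fell by 4.34 ± 0.30 and fell by 3.90 ± 0.69 (adjusted p 6.6e-06 and 0.00297), with Hbe1 going from 3884 ± 3231 to 260.1 ± 50 CPM. Of 10595 tested genes edgeR called 2148, 1379 higher and 769 lower at GD21. Other large rises were in Tnni1 (5.70 ± 0.51), Glyatl1 (5.60 ± 0.29), Serpina3c (5.55 ± 0.42) and Rbp2 (5.41 ± 0.24), and other large falls in Arhgap36 (−4.38 ± 0.65), Serpina6 (−2.76 ± 0.24) and Cited1 (−2.69 ± 0.30). Using controls of study block 143 or 140 alone at GD18, the change was 8.91 or 7.41 for Azgp1, 3.53 or 3.64 for Fgg, −4.21 or −4.51 for Hbg1 and −2.71 or −4.59 for Hbe1. The count was 1072 without control fetus 2130.

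By camera with its preset correlation 21 of 33 lists differed between the ages, and 16 did with an estimated one. Acute phase proteins had 18 members that rose of 19 (18 adjusted over the list alone) and a median log2 change of 3.36 (adjusted p 1.33e-41, and 0.00629 with an estimated correlation). Complement and coagulation had 25 of 30 that rose, urea cycle and amino acid breakdown 18 of 25, gluconeogenesis and glycogen 15 of 19, mitochondrial beta-oxidation 15 of 23 and lipoproteins and lipid transport 13 of 17 (26, 20, 17, 20 and 15 adjusted over the list alone). Bile acid synthesis and transport, thyroid hormone handling and response, and peroxisomal beta-oxidation had 8 each, mature hepatocyte genes 9 of 14, PPAR-alpha lipid targets 10 of 26 with 1 that fell, and growth hormone, prolactin and IGF axis 7 of 12 (9, 8, 9, 11, 13 and 8 that rose adjusted over the list alone). Macrophage and Kupffer cell markers had 6 of 11, ketogenesis 2 of 4 and AhR targets 2 of 2. Cell cycle had 11 members that fell of 25 (14 adjusted over the list alone), among them Mcm3 by −1.44 ± 0.26 and Ccna2 by −1.22 ± 0.22. Among those that rose, Fbp1 of gluconeogenesis rose by 4.14 ± 0.32, Vnn1 by 3.52 ± 0.25, Cyp4a3 by 3.08 ± 0.32, Cyp4a2 by 2.90 ± 0.23 and Ehhadh by 2.60 ± 0.32.

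With an estimated correlation, erythroid markers (7 fell, 17 not called), neutrophil and granulocyte precursor markers (8 rose of 11), ER stress and integrated stress response (7 rose, 1 fell), fatty acid synthesis (7 rose of 17) and liver endothelial markers (4 rose of 10) lost their camera call between the ages, at adjusted p = 0.135, 0.162, 0.0662, 0.135 and 0.135. Within them, Tal1 fell by 1.13 ± 0.15, S100a9 rose by 2.18 ± 0.29, Herpud1 by 1.58 ± 0.23 and Lpin1 by 2.77 ± 0.34. The remaining 12 lists had adjusted p of 0.0898 to 0.93: CAR and PXR targets, NRF2 targets, cholesterol biosynthesis, p53 and DNA damage, hepatoblast and fetal liver genes, immediate early and heat shock genes, and bile duct, lymphocyte, megakaryocyte, stellate and fibroblast, Y-linked, and pancreas, gut and placenta markers. The hepatoblast list, with 3 that rose and 4 that fell, and the p53 list had a median, mean or direction of opposite sign. The rise of Igf2 by 1.37 ± 0.17 and of Grb10 by 1.35 ± 0.19 ran against the fetal name of their list. The call of Ephx1 (0.98 ± 0.22) ended without fetus 2130 (adjusted p 0.0552), and that of Stab2, an endothelial receptor (1.45 ± 0.42), in 5 of the 9 fits that left out 1 library.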

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

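Of the tests of explanations below, that of genomic DNA was written before the result was seen, and those of dose, of a ceiling and of shared counts were chosen after it. The ceiling test replaced a planned one that compared counts of different probes.

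In 139 groups of 4 to 10 values, 7 held a library far from the rest, where chance gives about 1 in 20, or 6.95. Treated dam 2082 at GD18 had 2278 CPM of Acadm (765.6 to 808.8 in the other 3 dams at 30 mg/kg/d), 14.8 CPM of Hba-a2 (46.41 to 52.97) and 28 CPM of LOC100134871 (141.7 to 197.4). Treated dam 2127 had 207.1 CPM of Vnn1 (83.7 to 88.1). Among GD18 control dams, dam 2114 had 3.401 CPM of Cyp2b1 (20.7 to 58.1 in the other 5) and dam 2070 had 208.7 CPM of Hadha (250 to 265.6). Dam 2120 at 0.3 mg/kg/d had a total of 5002914 counts (6168366 to 6347654). No biological explanation was tested for these libraries.

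The 30 mg/kg/d response differed between fetus and dam at GD18, by a test of the difference itself, for Cyp4a3 (2.91), Cyp4a2 (2.69), Fabp1 (2.58), Hba-a3 (2.25), Fmo1 (2.21), Dhrs7l1 (−5.40), Slco1a4 (−3.24), Gdf15 (−2.80), Eci1 (−1.79) and Ephx1 (−1.50), as log2 values of fetus minus dam. At GD21 it differed for Fabp1 (2.82), Gsta2 (−3.10), Gstm7 (−2.22) and Ephx1 (−1.80). With dam as a replicate block the differences of Hba-a3, Slco1a4, Gdf15 and Eci1 at GD18, and all 4 at GD21, were no longer past the threshold.

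The first pattern weighed is the counts of genes silent elsewhere in the GD18 libraries of study block 140, such as olfactory receptors. Silent here means a mean of at most 0.5 counts per library in the other blocks. Control fetus 2129 of block 144 still held 365 CPM on receptor genes. Dose as the source of the difference between the blocks is excluded: the 6 control libraries of block 140 had at least 1087 CPM on receptor genes, and the 4 libraries of block 143 at 30 mg/kg/d at most 36.3 CPM. That bound replaced an earlier one on rank correlation with dose within the block, which reached a permutation p of 0.846 over 15 maternal and 0.0784 over 15 fetal libraries (0.846 and 0.157 adjusted over the 2; rho −0.05 and −0.47, Pearson r −0.14 and −0.46 with permutation p 0.619 and 0.0896, r 0.01 and −0.34 without 2 libraries). Neither bound shows that these counts were even over the doses within block 140. Its fetal controls had 1482, 3605 and 1087 CPM, and its fetuses at 30 mg/kg/d 469.7 and 194.7 CPM. Its control dams had 3211, 4350 and 3403 CPM, and its dams at 30 mg/kg/d 5530 and 4428 CPM. Genomic DNA carried into the libraries predicts fewer counts on silent X-linked genes in males. In 11 fetal libraries with Y-linked counts the count per silent X-linked gene, relative to silent autosomal genes, was 0.641 of that in 4 without (exact permutation p 0.000733, two-sided, the smallest that the 1365 regroupings can give). A candidate explanation is therefore genomic DNA. The higher X-linked ratio of maternal libraries (1.33) than of the 4 fetal ones without Y-linked counts (1.05) is left open.

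The second pattern is the rise of Fabp1, Cyp4a2 and Cyp4a3 in fetal and not maternal liver at GD18. Probes near a ceiling in the dam would hide a maternal rise. For Cyp4a2 and Cyp4a3 this is excluded as the whole cause: with both ages normalized together, the lowest 30 mg/kg/d dam at GD21 lay above the mean GD18 control dam by a log2 value of 1.06 for Cyp4a2 (198.7 against 95.1 CPM) and 1.09 for Cyp4a3, while the upper 95% bounds of their maternal log2 fold changes at GD18 were 0.196 and 0.192. For Fabp1 the same value was −0.097, with a bound of 0.448, so it shows no such room and a ceiling stays open. The spread of its maternal GD18 level, from 3462 to 9387 CPM over 30 libraries (SD 0.282 of the mean), speaks against a ceiling at the control level, but single libraries do not exclude one. Counts shared between Cyp4a2 and Cyp4a3 leave their sum unchanged, and the sum differed between fetus and dam by 2.82 ± 0.36 (adjusted p 4.73e-06), which excludes sharing as the whole cause. The ratio of their counts kept to 0.606 to 0.688 in the maternal libraries, so which of the copies rose is left open. With fetal sex, inferred from Y-linked counts, as covariate the fetal rises were 2.51, 2.23 and 2.44 for Fabp1, Cyp4a2 and Cyp4a3. A fetal response of Cyp4a2 and Cyp4a3 that the GD18 dam lacks may be biological, as a hypothesis; age and tissue differences between dam and fetal liver stay untested.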

How the results depend on the processing

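The alternatives named here were chosen before the data were examined, except the covariates, the omission of library 2135 and the slopes within a study block, which were chosen after seeing the data. No named gene value and no list result was scored as reversed. A count of genes has no sign, so it could not be scored in this way. The balance of higher and lower genes did change in some fits. Fetal GD18 liver at 30 mg/kg/d had 13 genes higher and 0 lower. Most of the 260 genes called there with fetal sex as covariate were lower. Fetal GD18 slopes were upward for 8 of 11 genes, and for 46 of 858 without fetus 2079. Of 548 counts under an alternative 436 stayed within 1.5 times, 16 fell to 0, 29 rose from 0 and 67 moved. Of 3279 values of named genes 2894 stayed on their side of the threshold, 353 fell short of it and 32 passed it, and of 656 list results 586 stayed, 56 fell short and 14 passed. DESeq2 gave no adjusted p for 1 named-gene value. With RLE factors all counts stayed within 1.5 times. Fitting fewer libraries can lower a count, but some counts rose with fewer libraries, and the cause was not tested. Fetus 2079, without which 858 slopes were called, had 4852 CPM on receptor genes. Dam 2078, without which 100 genes were called at 3 mg/kg/d, had 2839 CPM. That left dam 2079, at 663 CPM, as the dam of that dose in block 140. Maternal GD21 counts at 30 mg/kg/d also rose, to 55 without dam 2141, in libraries with at most 34.8 CPM on receptor genes.

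Within study block 143 the counts in maternal GD18 liver were 1 at 0.1 mg/kg/d (0 with both blocks), 0 at 10 (6), 29 at 30 (63) and 19 for slopes (30), and in fetal GD18 liver 1 at 3 mg/kg/d (0), 4 at 30 (13) and 0 for slopes (11). Within study block 140 they were 2 at 3 mg/kg/d (0), 0 at 10, 13 at 30 and 11 for slopes in maternal liver, and 3 at 30 and 0 for slopes in fetal liver. With no block term maternal GD18 liver had 0 genes at 10 mg/kg/d and 30 at 30.

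By DESeq2 maternal GD18 liver had 11 genes at 3 mg/kg/d (0 by edgeR), 199 at 30 (63) and 129 slopes (30), and fetal GD18 liver 3 at 0.1 mg/kg/d (0). Maternal GD21 liver had 4 at 1 mg/kg/d, 5 at 3, 89 at 30 (31) and 83 slopes (41). Fetal GD21 liver had 1 at 3 mg/kg/d, 11 at 10, 26 at 30 (3) and 27 slopes (17). Responses of dam and fetus differed for 94 genes at GD18 (14) and 7 at GD21 (4), and fetal responses between ages for 2 (0).

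With no low count filter maternal GD18 liver had 1 gene at 3 mg/kg/d. Maternal GD21 liver had 186 at 1 mg/kg/d, 79 at 3, 62 at 10 (5) and 215 at 30, and fetal GD21 liver 20 at 1 mg/kg/d, 136 at 3, 54 at 10 and 66 at 30. Dam and fetus differed for 49 genes at GD21, fetal controls for 1429 (2148), and 15 lists (9) were called in fetal GD18 liver.

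From control and 30 mg/kg/d libraries alone, 18 genes were called in maternal GD18 liver and 0 in fetal GD21 liver. In the regroupings below, fitted from the same libraries, 299 genes differed between dam and fetus at GD18 (14 with every dose in the fit). With dose in mg/kg/d as score there were 311 slopes in maternal GD18, 24 in fetal GD18 and 123 in maternal GD21 liver. Without the 30 mg/kg/d group there were 6, 0 and 4, and 5 in fetal GD21 liver. With dam as a replicate block 0 genes differed between dam and fetus at GD21, and the count at GD18 stayed within 1.5 times (10).

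With the receptor share as covariate maternal GD18 liver had 1 gene at 0.3 mg/kg/d, 0 at 10 and 65 slopes, fetal GD21 liver had 11 slopes, and 1 gene differed between dam and fetus at GD21. With fetal sex, inferred from Y-linked counts, as covariate fetal GD18 liver had 151 genes at 10 mg/kg/d and 260 at 30, and with sex and the receptor share together 0 and 11. With the haemoglobin share as covariate fetal GD21 liver had 4 genes at 1 mg/kg/d, 4 at 3 and 13 at 10. With library 2135 left out as well it had 4, 8, 52 and, at 30 mg/kg/d, 7.

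With an estimated correlation 5 lists (11) were called in maternal GD18, 4 (8) in maternal GD21 and 2 (13) in fetal GD21 liver, and by fry 4 in maternal GD21 and 0 in fetal GD21 liver.

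With 1 library left out at a time, maternal GD18 counts ran from 0 to 1 at 1 mg/kg/d, 0 to 100 at 3, 0 to 7 at 10, 23 to 124 at 30 and 20 to 45 for slopes. Fetal GD18 counts ran from 9 to 12 at 30 mg/kg/d and 9 to 858 for slopes. Maternal GD21 counts ran from 3 to 6 at 10 mg/kg/d, 10 to 55 at 30 and 19 to 53 for slopes, and fetal GD21 counts from 0 to 20 at 30 mg/kg/d and 7 to 27 for slopes. Differences of dam and fetus ran from 7 to 17 at GD18 and 0 to 3 at GD21, differences between ages from 0 to 0 in maternal and 0 to 5 in fetal liver, and fetal controls from 1072 to 2480. The other doses stayed at 0.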

Other observations

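Of the tests below, those of shared controls and of maturation were chosen after the result was seen, and the counts of splits were planned. The first replaced a bound of at least 10 of the 13 genes, which could not be reached because only 9 had risen with all controls, and then a count among the 13 genes, which had been called with all controls. The second replaced a planned slope over genes that left out the called ones.

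The third pattern weighed is that 9 of the 13 genes that rose in fetal GD18 liver at 30 mg/kg/d also rose from GD18 to GD21 in fetal controls, where independent lists would share 1.65. Both comparisons use the GD18 controls. Of the 13 genes of smallest p that rose within block 140 alone, 7 rose with age by the controls of block 143, and of the 13 within block 143 alone, 6 did by those of block 140, against 95th percentiles of 4 and 3 in random lists. No GD18 control serves both comparisons there, which excludes shared control libraries as the whole cause. Treated fetuses further along in maturation would raise the maturing genes alike. Over all genes that rose with age, called ones kept, the slope of effect on age change was 0.037 in block 143 (1014 genes, −0.033 to 0.037 over 10 splits) and −0.001 in block 140 (1106 genes, −0.024 to 0.025). The slope in block 143 was the highest of its splits. The 4 genes that were called within 1 block and rose with age, with their effect taken in the other block, had ratios of effect to age change of 0.64 ± 0.081 (SE, Cyp4a3) or more. General maturation in equal proportion is therefore excluded as the whole cause for these 4 genes. Among the 9 genes the lowest ratio, over all libraries, was 0.225. Acot1 and Cyp3a23/3a1 rose at 30 mg/kg/d without a rise with age (−0.09 and −1.37). The median log2 fold change at 30 mg/kg/d was 0.27 for acute phase proteins and 0.08 for gluconeogenesis and glycogen, whose medians rose by 3.36 and 2.42 with age. Other lists moved in both: mitochondrial and peroxisomal beta-oxidation, ketogenesis, and lipoproteins and lipid transport had medians of 0.35, 0.36, 0.42 and 0.23 at 30 mg/kg/d and 1.42, 1.14, 1.00 and 1.16 with age. One possible explanation left, which was not tested, is an early rise of those fatty acid genes that rise with age. It would not cover Acot1, and age stays confounded with study block.

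Regroupings of the libraries of a comparison show whether chance can give as many genes; those for a dose use only control and treated libraries, so the real counts differ from those of the full fits. In maternal GD18 liver chance is excluded at 30 mg/kg/d (18 genes, 1 of 100 splits as large, highest other 1) and for slopes (30, 1 of 100, highest other 1). At 3 mg/kg/d 5 genes, with 1 of 100 splits as large and 4 as the highest other, exclude it for these libraries alone by a margin of 1 gene, while the full fit called 0 genes there and 0 to 100 with 1 library left out. It is not excluded at 10 mg/kg/d (1 gene, 12 of 100, highest other 4) or for the number of lists (10, 5 of 100, highest other 11). At 1, 0.3 and 0.1 mg/kg/d the real count was 0, so all 100 of 100 splits are as large by construction and decide nothing (highest others 4, 5 and 2). In fetal GD18 liver chance is excluded at 30 mg/kg/d by the share of splits (12 genes, 2 of 100), although another split gave 47. It is not at 10 mg/kg/d (1, 15 of 100, highest other 5), for slopes (11, 7 of 100, highest other 2122) or for lists (9, 10 of 100, highest other 12). At 3, 1, 0.3 and 0.1 mg/kg/d, with 0 genes each, 100 of 100 splits are as large by construction (highest others 10, 3, 1 and 1267). The split with 47 genes sets the treated fetuses 2082 and 2083 of block 140 on 1 side, with controls 2114 and 2115 of block 143. It keeps the dose contrast of block 140, but leaves the treated fetuses 2127 and 2128 of block 143 with the controls. Dose therefore runs the other way in block 143, and the source of the 47 genes was not tested. The splits with 1267 and 2122 genes point to a structure of the fetal GD18 libraries other than dose. They set as treated in block 140 the fetuses 2070 and 2073 (3605 and 5323 CPM on receptor genes) and, at the top dose, 2074 and 2079 (3365 and 4852 CPM), the 4 highest of that block.

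At GD21 slopes exclude chance in maternal liver (41, 1 of 100 splits, highest other 2) and in fetal liver (17, 1 of 100, highest other 1). The 10 splits of 3 against 3 libraries are too few for single doses. In maternal liver the real counts and highest others were 34 and 2 at 30 mg/kg/d (1 as large), 6 and 5 at 10 (1), 4 and 4 at 3 (3), 0 and 3 at 1 (10), and 9 and 12 for lists (3). In fetal liver they were 0 and 2399 at 30 mg/kg/d (10), 2 and 2 at 10 (2), 1 and 1 at 3 (3), 0 and 1 at 1 (10), and 16 and 18 for lists (2). The split with 2399 genes sets fetuses 2129, 2130 and 2141 against 2131, 2142 and 2143, which points to a structure of the fetal GD21 libraries that crosses dose. It follows the haemoglobin share, at 16%, 12.8% and 14.2% on 1 side and 3.96%, 5.12% and 5.09% on the other. Where the real count was 0, all 10 splits are as large by construction.

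For the difference between dam and fetus at GD18 chance is not excluded (299 genes without the other doses in the fit, 6 of 100 splits as large, highest other 608), and at GD21 the 10 splits are too few (1 gene, 2 as large, highest other 682). Differences between ages had 0 genes in maternal liver (highest other 21) and 0 in fetal liver (highest other 1462), where 100 of 100 splits are as large by construction. The split with 608 genes is the one with 47 above. That with 682 is the one with 2399 above, and the split with 1462 genes again sets 2129, 2130 and 2141 apart; both point to a structure of the samples. For fetal controls of both ages chance is excluded for the genes (2148, 1 of 84, highest other 565) and not for the lists (21, 8 of 84, highest other 25).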
